A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

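DRIP-seq, an immunoprecipitation of DNA with the S9.6 antibody against RNA:DNA hybrids, was carried out on asynchronous, mid-log budding yeast (Saccharomyces cerevisiae, strain WRBb-9D) grown in rich medium at 30 °C. Per the labels, spooled genomic DNA was cut with a mix of restriction enzymes, a part was kept as input, and both the immunoprecipitate and the input went through a round of whole-genome amplification before libraries of 200 bp fragments were made for an Ion Torrent PGM instrument. The series holds 1 immunoprecipitate (the S9.6 IP) and 1 input. The peak list of the S9.6 IP was analysed, and the input has no values of its own here.

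Per the submitters' processing notes, SAMtools 1.7 and MACS2 2.1.1.20160309 were used and the build was sacCer3. The aligner, the treatment of reads with several matching locations, the peak threshold and the way the input entered the calls are not given in the sources used here. The deposited list holds 1723 peaks with a start, an end, a summit and a whole-number score from 13 to 2084. The score is the authors' value, its scale is not given in the sources used here, and it was used only to rank and filter peaks within this list. The deposited columns for fold enrichment, p and q hold 0 for every peak and were not used. All 1723 starts and 1722 of the ends are multiples of 25 bp, and no peak is shorter than 200 bp. Read counts and depth are unknown, so no interval that needs them is given. With 1 IP library there is no replicate check on any value below, and no p-value is given across peaks or genes.

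Genes came from a RefSeq gene table of the R64 assembly, which is the sacCer3 sequence, with 6431 nuclear and 46 mitochondrial genes. Strands were read from the systematic gene names. Each chromosome was taken to run to its last gene or peak end, which gave 12061503 nuclear bp. Coordinates are 1-based sacCer3 positions. The positions of rDNA copies and transposons are those of the reference, and their number in the strain studied is not known from these data. The gene table gives no genome sequence, origins, centromeres, introns, long terminal repeats, telomeric elements or transposon annotation, so the planned tests of GC content, base composition, orientation to replication and those classes were not run.

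A gene counted as covered when at least 50% of its length lay inside peaks. For genome classes, profiles and chromosome ends, the nuclear peaks were placed at random 10000 times on their own chromosome with their lengths kept and without overlap. A value was called higher or lower when it lay outside the central 99% of the placements. For gene lists, the number of covered members was set against 10000 random lists of protein-coding genes with the same size and length deciles. Across 17 lists, no more than 0.17 calls would be made by chance. A list whose random range begins at 0 cannot be called lower, which makes that number smaller. The 16 gene lists and most alternatives were fixed before the data were examined, and a list of the genes within 30 kb of a chromosome end came from the annotation. Predictions for 3 of the 8 tests of explanations were recorded as written beforehand. For few tRNA genes and Ty elements near the ends, the alternative used was chosen after seeing the data. That test therefore does not count as fixed in advance. In the hexose transporter, amino acid biosynthesis and cell wall lists, 1 name each did not match a gene of the table. Shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error only. The named genes are the gene with the most overlap for each of the 25 nuclear peaks of highest score, up to 4 covered members of highest score and up to 2 longest untouched members of each fixed list, and a fixed set of strain, title and reference genes (BAR1, YRA1, RRM3, TDH3, ADE2, CAN1, HIS3, LEU2, TRP1, URA3, TLC1, SCR1, RDN37-1, RDN37-2, PMA1, ACT1). Other genes named in the text were chosen after their values were seen. So were the groups of long ORFs, which are ORFs over 5000 bp outside the chromosome ends that have no gene name of their own and share their length with another such ORF, and the classes of gaps between genes.

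Alternatives were the 847 nuclear peaks with a score of 24, the median, or more, any overlap (1 bp) or at least 90% in place of 50%, a circular shift of each chromosome's peaks, leaving out 30 kb at each chromosome end and the rDNA locus, and the 200 bp around each summit with any overlap. Alternatives chosen after seeing the data were the 840 nuclear peaks with a score under 24, leaving out the 181 peaks that touch a tRNA gene or an ORF of a Ty element, and leaving 91 Ty ORFs out of the gene set. Each alternative that moved or left out peaks or genes used 2000 placements or lists. The code was tested on 200 simulated peak sets: 1.04% of classes and 0.471% of lists were called where nothing had been planted. Lists of 20 genes with 35% of the members planted as covered were called in 100% of the simulated sets, with 20% planted in 60.5% and with 10% planted in 7.5%. For lists of 60 genes the shares were 100%, 100% and 51.5%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.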

Results

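DNA bound by S9.6, an antibody against RNA:DNA hybrids, was mapped by DRIP-seq in budding yeast. The labels call the yeast wild type, though BAR1 is deleted and RRM3 tagged in the strain. The strain also carries a GPD promoter, whose source is TDH3. There was 1 immunoprecipitate beside 1 input, and no further control of what the antibody bound. The series title concerns R loops bound by the mRNA export adaptor Yra1, collisions between transcription and replication, and telomeres. The comparisons below ask which genes and chromosome regions the deposited peaks of this one library lay over, relative to random positions. The list held 1687 nuclear and 36 mitochondrial peaks. Nuclear peaks had a median width of 325 bp, with a middle range from 225 to 475 bp and a longest peak of 12575 bp. They took up 7.37% of the nuclear genome, from 4.91% of chromosome IX to 10.2% of chromosome XII. The median nuclear score was 24 and the highest 679. Scores repeated often: 459 peaks scored 15, 218 scored 32 and 200 scored 26. Of the nuclear peaks, 1390 touched a protein-coding gene and 262 touched no annotated gene.

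Peaks lay over ORFs of the length of Ty1 and Ty2 retrotransposons, tRNA genes and snoRNA genes more often than random placement gave. The 26 long ORFs of 5269 or 5272 bp, the length of the Gag-Pol frame of Ty1 elements, were all covered, with a median of 91.9% of their length inside peaks and a lowest value of 72.3%. Their bases were inside peaks 11.8 times as often as in the placements, where the central 99% ran from 0.363 to 2.04. The 10 ORFs of 5314 bp, the length of the Ty2 frame, were less covered, with a median of 42.9% and a fold of 6.10 (range of placements 0.173 to 2.81). The 2 ORFs of 5410 bp, the length of the Ty4 frame, had 8.32% and 0% inside peaks, within the placements. With 200 bp around the summits in place of whole peaks the folds fell to 2.25 for the ORFs of 5269 or 5272 bp and to 3.001 for those of 5314 bp, both above the placements. Near-identical copies share reads, so the value of each single Ty ORF is uncertain. The number of Ty copies in the strain, the treatment of reads with several matching locations and the use of the input are not known. Whether copy number adds to the folds of these ORFs as groups was therefore not tested. Of the 25 nuclear peaks with the highest scores (162 or more), 21 touched a Ty ORF, while those ranked 1 and 3, beside the rDNA, did not. Among the ORFs touched were YGR027W-B on chromosome VII (536057 to 541325; 91.9% inside peaks, highest score 252), YPL257W-B on chromosome XVI (56748 to 62016; 87.7%, score 247), YML039W on chromosome XIII (196628 to 201896; 87.7%, score 216), YBL005W-B on chromosome II (221330 to 226598; 96.3%, score 196) and YJR027W on chromosome X (472760 to 478028; 100%, score 193).

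Of 275 nuclear tRNA genes, 82 were covered (29.8%, 95% interval 24.5 to 35.6), against a mean of 20.8 in the placements, and their bases were inside peaks 3.81 times as often as placed (range 0.509 to 1.58). The 88 peaks that touched a tRNA gene had a median score of 49 and a median width of 800 bp. The 107 peaks that touched a Ty ORF had 80 and 1375 bp, and the nuclear peaks that touched neither had 23 and 300 bp. These calls rested on peaks of higher score: in the 840 nuclear peaks with a score under 24, the fold was 0.776 for tRNA genes and 0.703 for snoRNA genes, within the placements, and 0.112 for the ORFs of 5269 or 5272 bp. ERV14 on chromosome VII (400871 to 401287), which encodes a cargo receptor of COPII vesicles, was the gene most overlapped by the 25th peak by score (401001 to 402525, score 162), which also touched a tRNA gene.

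Of 76 snoRNA genes, 19 were covered (25%, interval 15.8 to 36.3; mean of placements 5.77), with a fold in bases of 4.36 (range 0.111 to 2.41). SNR30 on chromosome XII (198784 to 199389), needed for processing of 18S rRNA, lay wholly inside a peak with a score of 141. The snoRNA cluster on chromosome XIII from SNR76 to SNR72 (297725 to 298651) lay inside a single peak with a score of 43. With 200 bp around the summits, the snoRNA fold was 2.47, within the placements. Among 6 snRNA genes, LSR1, the U2 snRNA (chromosome II, 680688 to 681862), lay wholly inside the peak with the sixth highest nuclear score (246; 678726 to 683850), and SNR19, the U1 snRNA, was 56.0% inside peaks. The other 4 were not touched, and of these SNR7-L and SNR7-S are overlapping entries of the same locus (chromosome VII, 939459 to 939672). The 2 of 6 covered lay within the placements (range 0 to 50%). The fold in snRNA bases was 9.55 (range 0 to 8.50), and 2.88, within the placements, around the summits. SCR1, the RNA of the signal recognition particle (chromosome V, 441987 to 442508), lay wholly inside a peak with a score of 130. TLC1, the telomerase RNA (chromosome II, 307587 to 308887), was 24.0% inside peaks, with a score of 17. NME1, the RNA of RNase MRP, was 55.6% inside peaks (score 38) and RPR1, the RNA of RNase P, had no peak. These 4 RNA genes belong to none of the classes tested. A class of 28 further noncoding and antisense RNA genes was within the placements (fold 0.291).

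**Figure D1:**
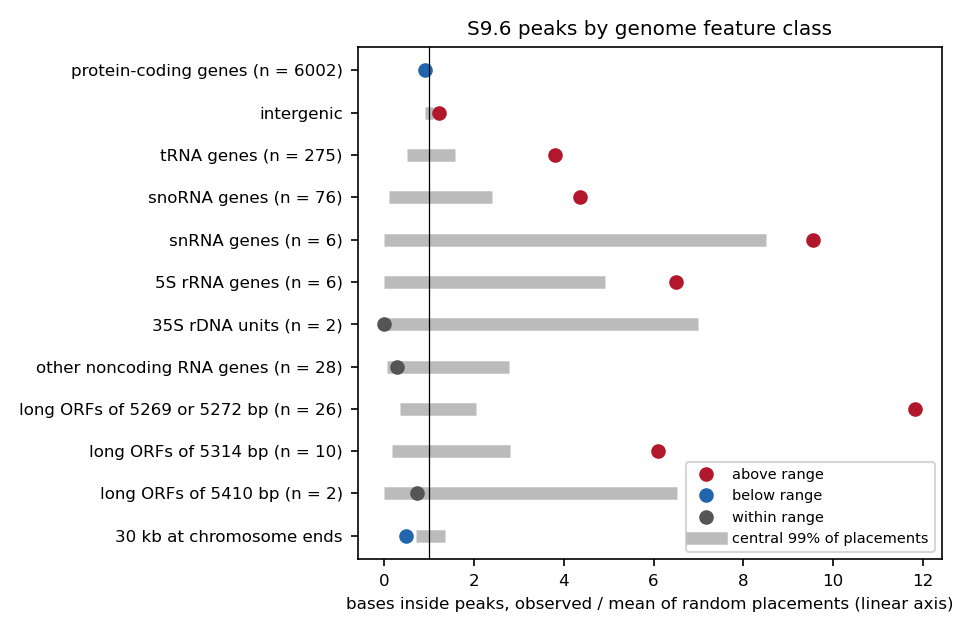
Fold of bases inside peaks over the mean of 10000 random placements, for 12 classes of the nuclear genome on a linear axis. Points are the observed values and grey bars the central 99% of placements. The long ORFs of 5269 or 5272 bp (fold 11.8), tRNA genes (3.81) and snoRNA genes (4.36) lie above their bars, and the 30 kb chromosome ends (0.479) below.

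Bases in protein-coding genes were inside peaks less often than placed (fold 0.911, range 0.966 to 1.03) and intergenic bases more often (1.22, range 0.916 to 1.09). Without Ty ORFs as genes, whose bases then count as intergenic, the folds were 0.660 and 1.82. Of 6002 nuclear protein-coding genes, 265 were covered (4.42%, interval 3.91 to 4.97; 4.44% in the placements, within their range), and 1274 were touched, fewer than the placed mean of 1490. The share covered was also below the placements with at least 90% of the length (fold 0.754), under a circular shift (0.877) and around the summits (0.892). Of the 265, 64 were Ty ORFs. Gaps between convergent genes had a fold of 1.40 (range 0.791 to 1.25), gaps between divergent genes 1.23 (0.832 to 1.19) and gaps between genes in tandem 1.11 (0.865 to 1.14). Gaps in tandem rose above the placements without the 30 kb ends and the rDNA (1.19), around the summits (1.22) and without peaks at tRNA genes or Ty ORFs (1.19). Without Ty ORFs as genes, whose bases then fall in gaps, the folds were 1.40 for convergent, 1.92 for divergent and 1.84 for tandem gaps, so the order of the 3 kinds turned.

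Glycolytic and fermentation genes stood out among the protein-coding lists. Of 20, 7 were covered (35%, interval 15.4 to 59.2), against a mean of 0.796 in random lists of matched length, and none of the 20 had a tRNA gene or Ty ORF within 1 kb. TDH3, the main glyceraldehyde-3-phosphate dehydrogenase (chromosome VII, 882812 to 883810), lay wholly inside a peak with a score of 100. ADH1, the fermentative alcohol dehydrogenase (chromosome XV, 159548 to 160594), also lay wholly inside a peak, with a score of 52. FBA1, the aldolase (chromosome XI, 326408 to 327487), was 82.7% inside peaks (score 61), and ENO2, an enolase (chromosome VIII, 451327 to 452640), 75.3% (score 80). PFK1 and PFK2, the 2 subunits of phosphofructokinase, had no peak. TDH3 and ENO2 have near-identical paralogs, so their values are uncertain where reads could be shared. The strain's GPD promoter also comes from TDH3, and the TDH3 peak (882301 to 884650) extends beyond the gene's start at 883810. Whether reads from that promoter add to this peak was not tested. The fold of 8.79 was 2.72 with any overlap, 3.10 around the summits and 15.0 without peaks at tRNA genes or Ty ORFs, all above the random lists. With at least 90% of the length required, the fold was 9.31, within the random lists.

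Ribosome biogenesis genes were the other fixed list called. Of 50, 7 were covered (14%, interval 5.82 to 26.7; mean of random lists 1.90). The 4 of highest score were DRS1, an RNA helicase of the large subunit pathway (chromosome XII, 131729 to 133987; 85.1% inside peaks, score 93), NOP58, a core protein of box C/D snoRNPs (chromosome XV, 896825 to 898360; 78.2%, score 61), MAK16 (chromosome I, 100225 to 101145; 99.9%, score 52) and EBP2 (chromosome XI, 125759 to 127042; 59.7%, score 52). UTP22 and RRP12 had no peak. The call was lost in the 847 nuclear peaks with a score of 24 or more (fold 3.08) and with at least 90% of the length (fold 1.92).

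The other 14 fixed lists were within the random lists. For all of them but ribosomal proteins the random range began at 0, so none of these could have been called lower. Ribosomal protein genes had 9 of 137 covered (mean of random lists 6.96), among them RPS25A and RPL26B, both wholly inside peaks with scores of 54 and 52, while RPL7A and RPL7B had no peak. Translation factors had 2 of 30 (FUN12, the initiation factor eIF5B, 79.7%, score 89; TEF1, the elongation factor eEF1A, 74.1%, score 73). Plasma membrane and vacuolar pumps had 2 of 21: VMA4, a subunit of the vacuolar ATPase (53.7%, score 120), and PMA1, the plasma membrane proton pump (78.2%, score 46). The random lists also drew on Ty ORFs. Without Ty ORFs as genes, the fold rose from 1.88 to 9.85 for these pumps and from 1.59 to 2.46 for translation factors. For telomere and telomerase proteins it rose from 1.66 to 3.15. All stayed within the random lists. Chaperones had 1 of 28 (HSC82, an Hsp90, 66.0%, score 52). Cell wall proteins had 2 of 36 (MTL1 and CCW14) and were called higher when any overlap counted (fold 1.87). Covered genes numbered 2 of 55 in meiosis (NDJ1, under a peak that reaches a Ty ORF, and SPO19), 2 of 61 in subtelomeric families (PAU8 and PAU23) and 1 of 21 among telomere and telomerase proteins (TEN1, a subunit of the CST complex, 93.6%, score 43, under a peak that also holds a tRNA gene), with no peak over SIR4 or RAD50. No member was covered among 10 histone genes, 35 glucose-repressed and galactose genes, 19 hexose transporters, 69 amino acid biosynthesis genes (mean of random lists 2.82), 34 long genes and 25 factors of R-loop metabolism and mRNA export. Untouched genes in these lists included SEN1, the helicase that unwinds RNA:DNA hybrids, SAC3, DYN1, NUM1, GLT1, ARO1, FOX2 and SIP4.

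**Figure D2:**
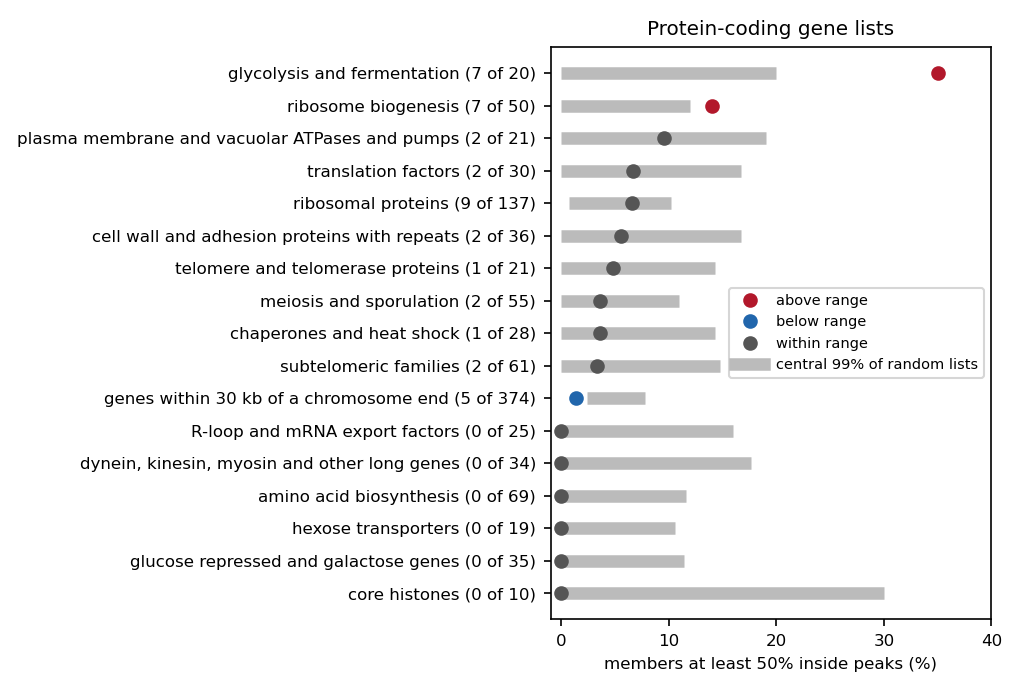
Percent of members with at least 50% of their length inside peaks, for 16 fixed lists and the genes within 30 kb of a chromosome end. Points are observed values and grey bars the central 99% of 10000 random lists of matched gene length. Glycolysis and fermentation (35%) and ribosome biogenesis (14%) lie above their bars and genes near the ends (1.34%) below.

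Among genes of the title and genotype, YRA1 (chromosome IV, 1236558 to 1238004) was 34.6% inside peaks with a score of 26, and RRM3, a helicase tagged in this strain (chromosome VIII, 170799 to 172970), 42.4% with a score of 71. BAR1, deleted in this strain (chromosome IX, 322342 to 324105), had 0.283% of its length inside a peak at 324101 to 324575, which lies mostly beyond the gene. That peak scored 114, the highest score on chromosome IX. Of the markers, LEU2 was 48.1% inside peaks (score 24), URA3 27.4% (score 23) and CAN1 14.1% (score 15), while ADE2, HIS3 and TRP1 had no peak. ACT1, the actin gene, was 8.42% inside peaks (score 19).

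The 2 copies of the 35S rDNA unit in the reference, RDN37-1 (chromosome XII, 451575 to 458432) and RDN37-2 (460712 to 467569), had no peak. Peaks were absent from 451151 to 469125, and the flanking peak began at 469126. In 7.07% of placements no peak base fell in the units, so 0 lay within the range. Directly beyond lay the 3 nuclear peaks of highest score. They ran from 469126 to 475725 (score 273), from 476001 to 488575 (score 318) and from 488751 to 490575 (score 679). They held ASP3-1, ASP3-2, ASP3-3 and ASP3-4, repeated asparaginase genes, the 5S genes RDN5-3, RDN5-4, RDN5-5 and RDN5-6, the Ty ORF YLR157C-B, and YLR162W, a small ORF with no name (489573 to 489929). The 5S genes RDN5-1 and RDN5-2, inside the peak-free stretch, had none. The 6 5S genes together had a fold of 6.51 (range 0 to 4.91), which was within the range under a circular shift (6.63) and 0 around the summits.

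**Figure D3:**
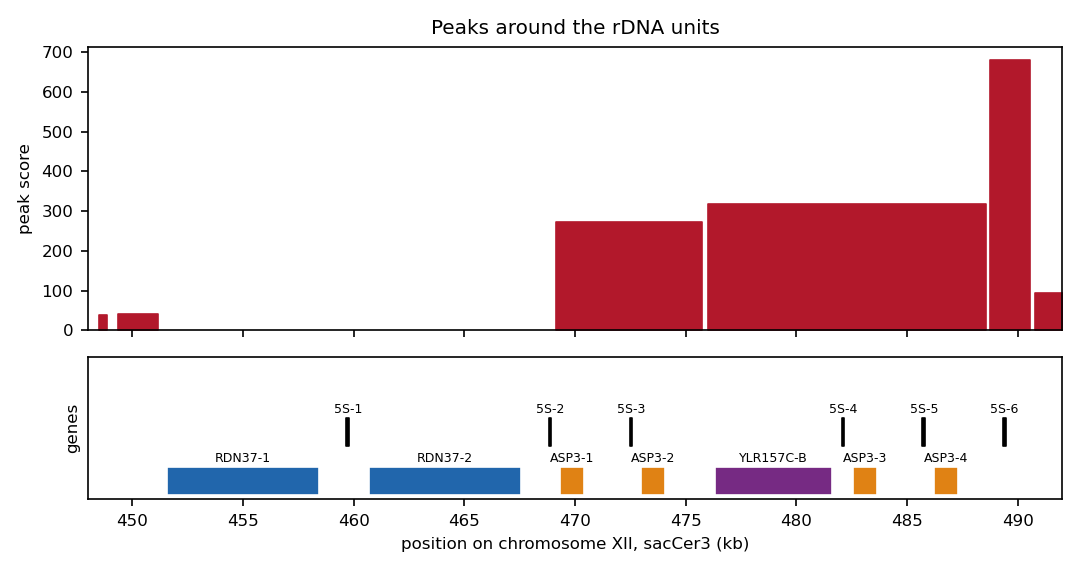
Peaks and selected genes on chromosome XII around the rDNA units. The upper part gives each peak's span in kb and its score, and the lower part the 35S units (RDN37), 5S genes, ASP3 genes and a Ty ORF. No peak lies over the 35S units, and the peak at 488751 to 490575 has a score of 679.

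Peaks were scarce towards chromosome ends. In the outer 30 kb, 3.43% of bases were inside peaks, against 7.17% placed (fold 0.479, range 0.7005 to 1.37), and 5 of 374 protein-coding genes there were covered (1.34%, interval 0.435 to 3.09; mean of random lists 17.9). Of the 9 bins of 5 kb between 5 and 50 kb, 6 were below the placements, with 1.61% at 25 to 30 kb. The outermost 5 kb differed: 8.31% of its bases were inside peaks, within the placements (fold 1.31, range 0.424 to 1.89), and 20 of the 32 ends had a peak there, with scores up to 52. Where a chromosome was taken to end at its last peak, as on chromosomes I and XI, a peak there was certain. The spans taken for chromosomes V, IX, X and XV are multiples of 25 bp, as peak ends are, so they probably ended at a peak too. The count of 20 ends and the fold of the outermost 5 kb may be raised by this. That fold was 1.12 under a circular shift, within the placements. It was 1.14 without the end that had most peak bases, which leaves the other such ends in. With the 840 peaks scoring under 24, the fold in the outer 30 kb was 0.906, within the placements. YRF1-1 and YRF1-6, helicase genes of subtelomeric Y' elements, had no peak. PAU8 (chromosome I, 1807 to 2169), a seripauperin gene, lay wholly inside a peak with a score of 26.

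Along 5093 protein-coding genes of 500 bp or more, coverage was higher near the end: 8.56% of bases in the last of 10 equal bins and 6.95% in the first were inside peaks, a difference of 1.61 percentage points (range of placements -1.37 to 1.36). Ty ORFs carried this difference. Without them it was 0.411 points, and without peaks that touch a tRNA gene or Ty ORF 0.585 points, both within the placements. By gene length, 8.03% of the shortest decile (51 to 393 bp) and 6% of the longest (2844 to 14733 bp) were covered, a difference of -2.03 points (placed -5.41, range -8.66 to -2.40). Of the 600 genes of the longest decile, 46 were Ty ORFs, and 2 of the others were covered. With all 91 Ty ORFs left out and the deciles drawn again, the difference was -7.84 points, within the placements.

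**Figure D4:**
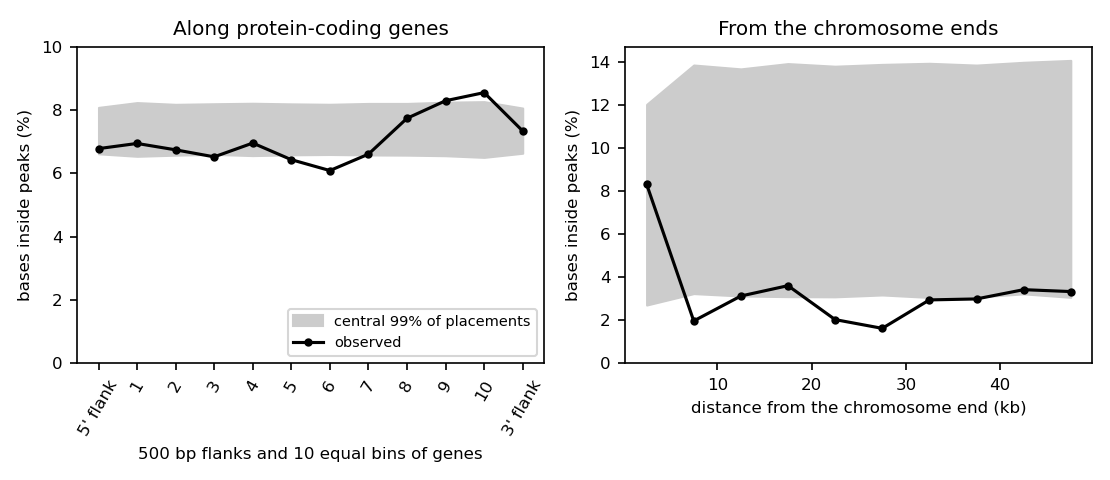
Percent of bases inside peaks along protein-coding genes (left; 10 equal bins and 500 bp flanks) and by distance from the chromosome end in kb (right). Lines are observed values and grey bands the central 99% of placements. The last bin of genes reaches 8.56%, and the bin from 25 to 30 kb falls to 1.61%.

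The mitochondrial chromosome held the highest scores of the list. Its 36 peaks took up 44.6% of its 85777 bp, and bases of protein-coding genes were inside peaks at 88.4%, 1.93 times the placed share (range 0.488 to 1.56), while 18.1% of bases outside genes were (fold 0.411, range 0.721 to 1.26). COX1, a subunit of cytochrome c oxidase (13818 to 26701), was 92.2% inside peaks, the highest of them with a score of 2084 at 13776 to 23375. The large rRNA gene (58009 to 62447) was 93.9% inside peaks (score 1816) and the small rRNA gene (6546 to 8194) 100% (score 1379), and the fold in bases of these 2 genes, 2.103, was within the placements (range 0.0723 to 2.20). COX2 scored 1483, COX3 1189, COB, the cytochrome b gene, 845, ATP6 554 and OLI1 518. ATP8 and VAR1 had no peak, and 8 of 24 mitochondrial tRNA genes were covered, with a fold of 0.776 within the placements. Mitochondrial DNA is present in many copies per cell, and how the input was used against it is not given in the sources used here.

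**Figure D5:**
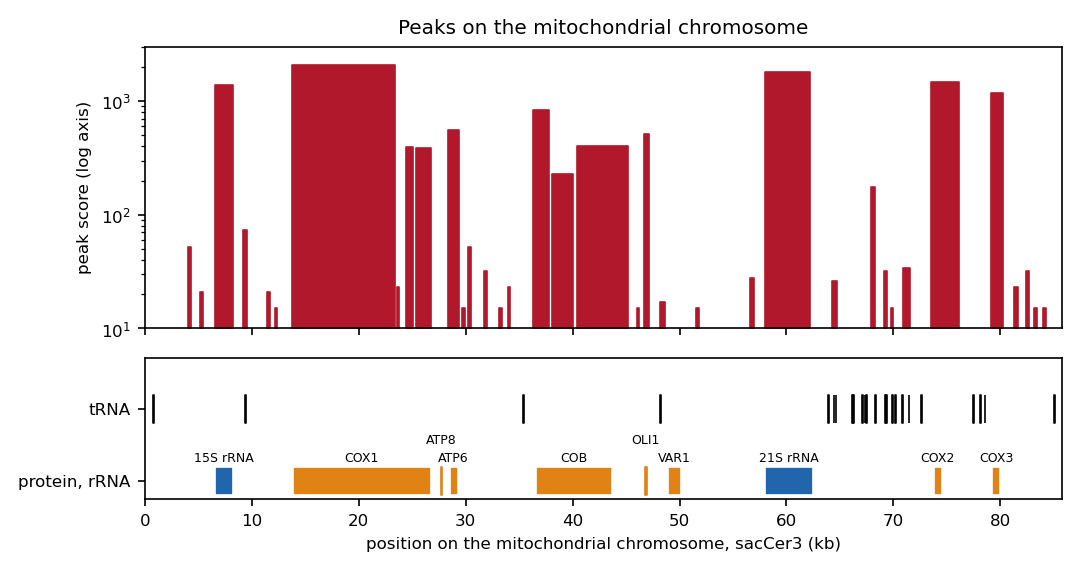
Peaks on the mitochondrial chromosome, with the score on a log axis (upper part) and genes (lower part) by position in kb. The peak over COX1 has a score of 2084 and that over the large rRNA gene 1816, and most tRNA genes have no peak.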

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

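No paired analysis was possible because the groups share only replicate number 1 and the values come from 1 peak list. The planned tests that need a genome sequence, origins, centromeres, introns, long terminal repeats, telomeric elements or transposon annotation were not run, nor was matching on GC content. Class bases, gene lists and the length and position differences were computed under the alternatives that apply to them. Features covered were not computed under the alternatives chosen after seeing the data. Named genes were computed again only with peaks scoring 24 or more. The cause of a change was not tested unless one is named. Peaks with a score of 24 or more numbered 847, took up 5.37% of the nuclear genome, and took the ribosome biogenesis fold to 3.08, within the random lists. Under a circular shift the 5S fold (6.63), the fold of ORFs of 5314 bp covered (10.6) and the length difference (-2.03 points) lay within the placements. Around the summits, the folds of the ORFs of 5269 or 5272 bp and of 5314 bp fell to 2.25 and 3.001, still above the placements, and folds within the placements were 2.47 for snoRNA, 2.88 for snRNA and 0 for 5S genes in bases and 0 for 5S genes touched, and the length difference was 33.6 points, within its placements. With any overlap the length difference was 30.0 points, below its placements, and cell wall genes were called higher (fold 1.87). With at least 90%, glycolysis (9.31), ribosome biogenesis (1.92) and genes near the ends (0.150) lay within the random lists, and the ORFs of 5314 bp had a fold of 0. Protein-coding genes covered, within the placements at first, were below them with any overlap (0.855), at least 90% (0.754), a circular shift (0.877) and around the summits (0.892).

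Of the alternatives chosen after seeing the data, leaving out peaks at tRNA genes or Ty ORFs took the 5S fold to 4.595, the length difference to -6.06 points and the position difference to 0.585 points, and leaving Ty ORFs out of the genes took the latter 2 to -7.84 and 0.411 points, all within range. Peaks with a score under 24 gave folds within the placements for tRNA (0.776), snoRNA (0.703), snRNA (3.11), 5S genes (0), the ORFs of 5314 bp (0.803) and chromosome ends (0.906), and below them for the ORFs of 5269 or 5272 bp (0.112), whose bases the higher peaks already take. Within range with those peaks were also glycolysis (25.6), ribosome biogenesis (7.04), genes near the ends (0.729), the length difference (-1.97 points) and the position difference (0.0868 points). The call was kept in 60 of 72 values for class bases, in 50 of 58 for features covered and in 125 of 133 for gene lists. Some of these changed direction within range. Examples were ribosomal proteins (1.29, and 0.938 with at least 90%) and the bases of ORFs of 5410 bp (0.724, and 1.53 around the summits). Of 93 named genes, 91 stayed on their side of 50% with peaks scoring 24 or more, and SPO19 and PAU23 fell to 0%. That count was largely fixed in advance. Leaving out peaks cannot raise coverage, and many named genes were chosen for a high score or for having no peak.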

Other observations

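The tests of the peaks 30 to 50 kb from the ends and of named genes near the ends, the tests of explanations for the missing peaks over the 35S units, and the values for peaks with a score under 24 or without peaks at tRNA genes or Ty ORFs were chosen after the results or the data were seen. No biological explanation was tested, since the series has 1 immunoprecipitate and no condition to compare.

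Peaks of high and low score differed in where they lay. In the 840 nuclear peaks with a score under 24, tRNA genes (fold 0.776), snoRNA genes (0.703) and chromosome ends (0.906) were all within random placement, while in the 847 others the folds were 4.94, 5.61 and 0.310, all outside it. Gaps between convergent genes were above the placements in both sets, with folds of 1.57 and 1.33. Of the 5911 protein-coding genes that are not Ty ORFs, 372 lie within 1 kb of a tRNA gene, and these made up 46 of the 201 covered.

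tRNA genes were covered 82 times against 20.8 placed. Ty elements often lie beside tRNA genes, but the 224 tRNA genes with no Ty ORF within 5 kb still had a fold of 3.197 (range of placements 0.456 to 1.65), which argues against Ty ORFs as the whole cause. Peaks of low score also fail to account for it, since the fold rose to 4.94 in peaks with a score of 24 or more. Partial Ty elements and lone long terminal repeats, and reads shared between identical tRNA copies, were not tested and stay open. Conversely, the 7 ORFs of 5269 or 5272 bp with no tRNA gene within 1 kb were all covered, with a fold of 11.9 in bases, though around the summits their fold of 2.20 was within the placements (up to 2.24).

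Peaks were scarce near chromosome ends. Loss of reads in repeated subtelomeric sequence may account for part of this in the outer 30 kb, but 30 to 50 kb from the ends the fold was still 0.430 (range 0.654 to 1.45). In the outer 30 kb, 198 named genes outside the fixed repeated families had 1 covered, a fold of 0.125 against random lists (range 0.250 to 2.002). This goes against repeats, yet which of these genes have near copies is not known without the sequence, so that explanation cannot be told apart there. Few tRNA genes and Ty elements near the ends are not enough either, since without peaks at those features the fold in the outer 30 kb was 0.581, still below the placements (range 0.745 to 1.32).

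The 35S rDNA units had no peak while the repeats beside them had the highest nuclear scores. Whether the gap arose by chance could not be decided. At the reference positions, 7.07% of placements left the units empty. Of 1671 gaps between nuclear peaks, 174 were at least as long as this one of 17975 bp. Both values treat the units as single copies, and their number in the strain is not known. Of the 4 ASP3 and 6 5S genes in and beside the units, 8 lay wholly inside peaks, and the other 2, RDN5-1 and RDN5-2, had none. The 8 go against removal of every read with more than one location, but how alike these copies are in the strain is not known without the sequence, so that explanation stays open. Masking of the units in the authors' processing, or a match between IP and input at such a repeated locus, cannot be told apart from a true lack of signal, because the 17975 bp without peaks is the pattern itself.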
